A study of Mus musculus with 6 samples.

How the data were processed

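RNA from the soleus of mice that lack tenascin-C (Tnc) was measured on 6 arrays, 1 per animal, after 1 day of reloading. Per the labels' protocols, total RNA was extracted from sections of the muscle belly, reverse transcribed with gene-specific primers in the presence of a radioactive nucleotide, and hybridised as a single label. The labels give 1 group of 6 biological replicates. Replicates are numbered here in the order of the sample records, and that number names the array throughout. Unloaded, wild-type or sham animals were not analysed here, so no comparison between groups was made.

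The authors' deposited table holds 1 intensity per probe and array, on a linear scale, for 223 probes. No value was missing and none was 0 or below. The deposited intensities are relative values: without probes 1M and 1O, those of each array summed to between 0.995 and 0.999. The authors thus appear to have divided each array by the summed signal of its other probes; this was read from the values, since the step is not given in the sources used here. The image analysis and the treatment of background are not given there either. The lowest intensity differed between arrays, from 0.0006 to 0.003, and no background subtraction is visible in the values. Intensities carry 4 decimals, apart from 1 value, and 1 unit in the last decimal place was 3.33% of the lowest intensity of array 1 and 16.7% of that of array 6.

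Gene names came from the platform's annotation, matched through Entrez identifiers to a mouse gene table of assembly GRCm38.p6. Of the 223 probes, 205 had 1 gene symbol, 18 had none, and 0 had several. The identifiers of 204 named probes matched the table, and the symbol of the remaining 1 was kept as annotated. No coordinates are given, because the build behind the probes is not given in the sources used here. Probe 1O is annotated as 28S ribosomal RNA and 1M is unnamed; both lie outside the authors' scaling and were left out of the tests, which leaves 221 probes, 204 of them named for 202 genes. Fn1 and Igf1 have 2 probes each, named with both values; in gene lists those of Igf1 were averaged, and for Fn1 the measured probe 9D was used.

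The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. A probe counted as measured where it lay above the array's lowest intensity on all 6 arrays, and its log2 intensity was used with no further scaling. Hypervariable probes were sought with limma's squeezeVar, with a robust prior that follows the mean log2 intensity, by an upper-tail F test of each probe's variance against the prior and Benjamini-Hochberg adjustment at 0.05. For each fixed list with at least 3 measured genes, co-variation was tested with a one-sided permutation test. The variance over arrays of the mean of the members' standardized, array-centred values was set against 100000 shuffles of each gene's values. Relations between list scores were tested with two-sided exact permutation tests over 720 pairings. The median SD of each list was placed among 10000 random lists of equal size matched on mean log2 intensity; percentiles of at least 97.5 or at most 2.5 were counted. Of 22 lists, 4 had no probe on the array (developmental contractile, apoptosis, nerve and neuromuscular junction, erythrocyte and blood) and 3 had only 1 or 2 genes (slow contractile, Krebs cycle, adipocyte), which left 15 for tests. A planned test against a reference sample was not run, since the table holds signals of single samples.

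The rule for named genes took Tnc; the 8 probes with the largest and the 5 with the smallest SD among named measured probes; the 2 members of each tested list with the largest SD; for each co-varying list the 3 members that follow the others best; and up to 10 list members measured on no array, of which there were 0. Other genes named in the text were chosen after their values were seen, most of them because they reached 2 times the lowest intensity on each of arrays 3 to 6.

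The settings changed in turn were quantile normalization, median-centring, cyclic loess, a filter that removed the lower quartile of measured probes, log2 of the value plus a pseudocount of 0.0006 over all probes, a floor 2 times as high, another prior, unstandardized list scores, genes of 1 list only, and leaving out each array. After the data were seen, 4 more were added: arrays 3 to 6 alone; the same arrays with the lowest intensity subtracted, centred on the median, over probes at 2 times the lowest or more (called net values here); all 6 arrays with the lowest intensity subtracted; and probes 1M and 1O kept. Positions on the membrane were read from the probe identifiers, with the number as the row and the letter as the column. That layout is an assumption.

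The variance test and the list co-variation test were checked on simulated data. With the SD of 400 probe values raised 3 times, in sets of 197 probes, the variance test recovered 157, and with the SD raised 6 times it recovered 244; it called 1 and 3 of 3540 probes that were not raised. With a shared factor of 1 SD in 40 simulated lists, the permutation test recovered 37, and 4 of 100 lists without a factor were called. With a factor of 0.5 SD it recovered 20, and without a factor 0. In both simulations the noise was independent between probes, with no floor or place trend that differed between arrays. The deposited data have such features, so the rates of false calls do not carry over to them. The number of arrays limits the precision of each SD. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3 and limma 3.58.1 were used.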

Results

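The soleus, a slow postural muscle of the calf, was examined in mice deficient in tenascin-C, an adhesion-modulating glycoprotein of the extracellular matrix. The animals had been reloaded for 1 day, that is, returned to weight bearing after the muscle had been relieved of it. Transcript signals of 6 animals, 1 array each, were measured with a low-density array of 223 probes and a radioactive label. All 6 formed 1 group, so the data answer which of the probed transcripts were measurable in this muscle and how far signals differed between arrays. With 1 array per animal and no repeated array of an animal, differences between animals and between arrays cannot be told apart.

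The deleted gene was examined as a check of the labels. The Tnc probe gave intensities of 0.0122 and 0.0135 on arrays 1 and 2, and of 0.002, 0.0025, 0.0021 and 0.0013 on arrays 3 to 6. These were 4.07 and 4.50 times the array's lowest intensity on arrays 1 and 2, and 1.11, 2.78, 1.75 and 2.17 times it on the others. The mean log2 intensity was −8.11 ± 1.45 (SD, n = 6). Whether the probe lies in the deleted part of the gene is not given in the sources used here, so its signal does not test the genotype. In the grid read from the probe identifiers it lies 3.16 steps from probe 1M, a very bright spot on arrays 1 and 2. On array 4 probe 1M gave 3.05, against 0.570, 1.02 and 0.872 on arrays 3, 5 and 6.

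The arrays differed in the range they left for signals. Probes 1M (unnamed) and 1O (28S ribosomal RNA) together gave 41.3 and 40.5 on arrays 1 and 2, against 0.876, 3.21, 1.25 and 1.15 on arrays 3 to 6, in units of the summed signal of about 1 of the other probes. On arrays 1 and 2 the lowest intensity, taken over 221 probes, made up 66.6% of that sum, and 19 and 20 probes reached 2 times the lowest. On arrays 3, 4, 5 and 6 the lowest intensity made up 39.9%, 19.9%, 26.6% and 13.3%, and 37, 64, 77 and 104 probes reached 2 times it. Of 221 probes, 197 lay above the lowest intensity on all 6 arrays, 5 reached 2 times it on all 6, and 30 did so on each of arrays 3 to 6. The split of the arrays rests on 1M and 1O and was made after the data were seen; no test was run between the 2 sets.

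Contractile and sarcomeric genes were among those measured well above the lowest intensity. Myh7, the slow myosin heavy chain, reached 47.0 ± 25.8 times the lowest intensity (SD, n = 4, arrays 3 to 6), and 2.30 and 2.67 times it on arrays 1 and 2. All 3 fast myosin heavy chains on the array passed 2 times the lowest on each of arrays 3 to 6: Myh1 at 30.3 ± 21.1, Myh2 at 21.3 ± 13.1 and Myh4 at 11.4 ± 8.20 times (SD, n = 4). Of the 4 sarcomere scaffold and costamere genes, 3 did so. These were Des (desmin, an intermediate filament protein) at 39.8 ± 15.8 times, Ttn (titin, the elastic filament of the sarcomere) at 18.5 ± 12.8 times, and Itgb1 (a beta integrin subunit) at 7.38 ± 2.75 times. Itgav, an alpha integrin subunit, stayed between 1.17 and 1.56 times. Folds over the lowest intensity include background, so they are not compared between probes. The lowest intensity itself ran from 0.0006 on array 6 to 0.0018 on array 3. The SDs of folds, here and below, include differences in that divisor and are not a spread between animals alone.

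Genes of oxidative metabolism were measured in the same animals. Of 7 respiratory chain probes, the 4 subunits of cytochrome c oxidase passed on each of arrays 3 to 6, with Cox6a2 at 44.6 ± 22.4, Cox5b at 17.3 ± 10.7, Cox4i1 at 15.6 ± 7.54 and Cox8a at 5.51 ± 3.10 times the lowest intensity (SD, n = 4). Tfam, a transcription factor of mitochondrial DNA, lay between 1.22 and 1.42 times. Both Krebs cycle genes passed, Mdh2 at 4.62 ± 1.49 and Pdha1 at 5.13 ± 2.41 times. Of 13 lipid metabolism probes, 3 passed: Fabp4, a fatty acid binding protein also used as an adipocyte marker, Lpl, a lipase that releases fatty acids from circulating triglyceride, and Hadh, an enzyme of beta-oxidation. Fabp4 reached 5.55 ± 2.86, Lpl 3.61 ± 1.46 and Hadh 3.60 ± 1.44 times (SD, n = 4). Mb, the oxygen-binding protein myoglobin, reached 55.4 ± 35.1 times and was the only 1 of 5 stress and antioxidant probes to pass.

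Of 12 glycolysis and glycogen probes, 5 passed on each of arrays 3 to 6 and 4 on none. Aldoa (aldolase) reached 118 ± 84.0, Gapdh 112 ± 77.3, Ldhb (a lactate dehydrogenase subunit) 11.6 ± 7.41, Pgk1 4.59 ± 1.92 and Eno2 4.58 ± 0.974 times the lowest intensity (SD, n = 4). Hk1, Insr, Ldha and Slc2a1 stayed under 2 times it on all 4 of these arrays. Of 6 reference gene probes, Gapdh and the ribosomal protein gene Rps29 passed, the latter at 28.6 ± 17.1 times. Car3, a carbonic anhydrase of slow fibres that is in no list, reached 17.1 ± 10.2 times.

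**Figure D1:**
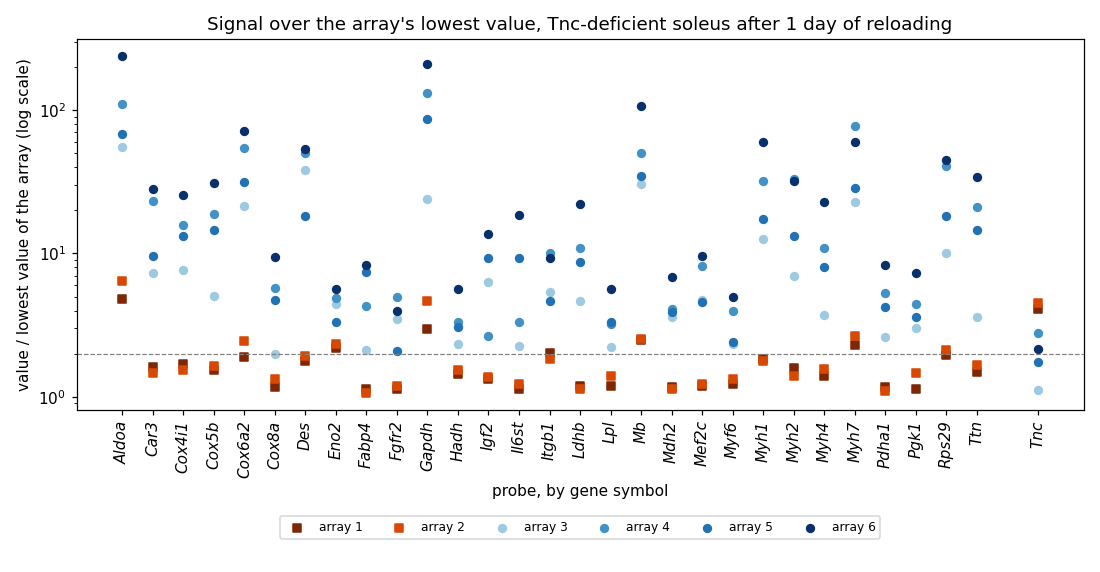
Intensity over the array's lowest intensity (log axis) for the 29 named probes that reached 2 times the lowest on each of arrays 3 to 6, and for Tnc; each point is 1 animal, squares are arrays 1 and 2, circles arrays 3 to 6, and the dashed line marks 2 times. For most of these probes the squares lie below the line, while the Tnc squares, at 4.07 and 4.50, lie above its circles.

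Matrix genes lay close to the lowest intensity. None of 12 extracellular matrix probes passed on each of arrays 3 to 6, and 6 passed on none of them, among them probes for Lama2, Lama5, Thbs1 and Thbs2. Tnxb, the relative of tenascin-C on the array, gave 2.19 ± 0.485 and Lamc1, a laminin chain, 2.40 ± 0.708 times the lowest (SD, n = 4). The 2 probes for Fn1 (fibronectin) differed, with 1.13 ± 0.215 at 4D and 2.01 ± 0.385 at 9D. Of 17 matrix proteolysis probes, 0 passed on each of these arrays and 13 on none, including the gelatinases Mmp2 and Mmp9. The protease inhibitors Timp2 and Timp3 passed on 2 of the 4 arrays each. All 3 protein breakdown genes, Capn3, Cast and Ctsh, stayed under 2 times the lowest on arrays 3 to 6.

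Among 27 myogenic and growth probes, 4 passed on each of arrays 3 to 6 and 9 on none. Igf2, an insulin-like growth factor, reached 7.99 ± 4.67 times the lowest intensity, the muscle transcription factors Mef2c and Myf6 6.77 ± 2.53 and 3.44 ± 1.29, and the growth factor receptor Fgfr2 3.65 ± 1.21 times (SD, n = 4). The regeneration markers Myod1 and Myog gave 2.01 ± 0.373 and 1.54 ± 0.370 times. Igf1 gave 2.37 ± 1.31 at probe 16I and 3.02 ± 1.33 at 22H. Il6st, the shared signalling receptor of the interleukin 6 family, was the 1 of 5 leukocyte and inflammatory probes to pass, at 8.40 ± 7.52 times, while the cytokines Il6 and Il1b lay between 1.06 and 1.56 times on these arrays. None of 19 angiogenesis and endothelium, 6 immediate early or 8 cell cycle probes passed on each of the 4 arrays, although 12, 4 and 4 of them did on some.

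Differences between arrays, 1 per animal, were described with the SD of log2 intensities. Over the 197 measured probes the median SD was 0.83 (n = 6). It was 0.29 once each array was centred on its median, since the array medians ran from −9.83 to −8.12 on the log2 scale. The largest SDs among named probes were those of Pole2 (a DNA polymerase subunit, 1.92), Gapdh (1.66 with a mean of −4.48), Top1 (topoisomerase, 1.60), Des (1.54), Tnc (1.45), Dgat1 (triglyceride synthesis, 1.44), Mb (1.43) and Cox6a2 (1.40). The smallest of these uncentred SDs were those of Acadl (0.15) and Lpl (0.20), both of lipid metabolism, and of Slc2a4, the insulin-responsive glucose transporter, Pgk1 and Myf6, each at 0.22. After median-centring Acadl gave 0.59, Lpl 0.57, Slc2a4 0.79, Pgk1 0.75 and Myf6 0.57, each above the centred median of 0.29. The large SDs had 2 forms. Gapdh, Des, Mb and Cox6a2 stood higher on arrays 3 to 6 than on arrays 1 and 2, while Pole2, Top1, Tnc and Dgat1 stood higher on arrays 1 and 2. Median-centring and quantile normalization left both directions, while after cyclic loess, which removes trends with signal, Gapdh, Des, Mb and Cox6a2 no longer differed that way.

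The net values of arrays 3 to 6 gave a median SD of 0.47 over 30 probes (n = 4). Igf2 had the largest SD, 1.35, which became 0.64 without array 4. It was followed by Fgfr2 at 1.17, Des at 1.04, Il6st at 1.00 and Eno2 at 0.92 among named probes, and without array 3 Des gave 0.67 and Eno2 0.43. Ldhb (0.05), Pdha1 (0.17), Myh4 (0.22) and Cox4i1 (0.26) had the smallest, with 0.01 for Ldhb without array 5, and 0.10 for Pdha1 and 0.15 for Cox4i1 without array 6. On arrays 3, 4 and 6 Ldhb was itself among the middle probes that set the array's median (net log2 −0.011, 0.0 and −0.028). So was Myh4 on arrays 4 and 6 (0.0 and 0.028). The small SDs of Ldhb and Myh4 are thus in part set by the centring, and do not show stable transcripts. Myh7 gave 0.69, Myh2 0.55 (0.09 without array 4) and Myh1 0.32 (0.11 without array 5). In limma's variance test on these values 0 of 30 probes passed, and 1 had an unadjusted p under 0.05. With array 4 left out as well, 1 of 35 passed, the unnamed 1C (SD 1.25, limma adjusted p = 0.0015), and 4 had an unadjusted p under 0.05; without array 3, 5 or 6 the count was 0.

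**Figure D2:**
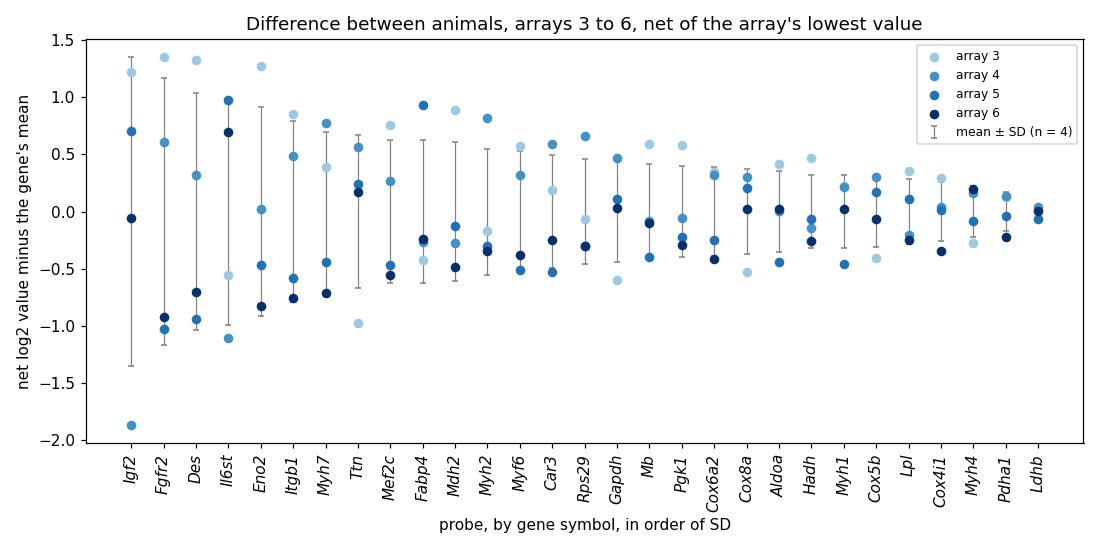
Net log2 intensity (lowest intensity subtracted, centred on the array's median) minus the gene's mean for the 29 named probes, in order of SD; each point is 1 animal of arrays 3 to 6 and bars are the mean ± SD (n = 4). The SD runs from 1.35 for Igf2 to 0.05 for Ldhb, which was among the probes that set the median on arrays 3, 4 and 6.

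With all 6 arrays and uncentred values, 4 of 197 probes varied more than other probes of like signal in limma's variance test. These were Top1 (SD 1.60, adjusted p = 0.00105), Tnc (SD 1.45, adjusted p = 0.00759), Dgat1 (SD 1.44, adjusted p = 0.0175) and Fgfr3, a growth factor receptor (SD 1.39, adjusted p = 0.0247). All 4 were higher over the lowest intensity on arrays 1 and 2 than on arrays 3, 4, 5 and 6, and lay within 4.0 grid steps of probe 1M, where 6 probes were tested. The array medians were also highest on arrays 1 and 2. In uncentred values that shift widens the SD of probes high there and narrows that of probes high on the other arrays. After median-centring 1 probe passed, and after quantile normalization or cyclic loess 0 did. Adjusted over the list alone, 2 extracellular matrix genes passed (Tnc and the laminin chain Lamb1), against 1 over all probes. The same held for 2 myogenic and growth genes (Fgfr3 and Igfbp1, against 1) and 1 lipid metabolism gene (Dgat1, also called over all probes), and 0 passed in the other 12 lists. Without array 1, 2 or 6 the count of calls was 0, and without array 3 it was 1. On arrays 3 to 6 alone the adjusted p of Tnc was 0.861, and over 16 settings it ran from 0.000627 to 0.916, with 5 of them under the threshold. On those arrays 4 of 200 probes passed, none of them among the 4 above: the unnamed 10C and 1C, Igfbp6, a binding protein for insulin-like growth factors (SD 1.33, adjusted p = 0.0133), and Ang, angiogenin (SD 1.22, adjusted p = 0.0303). Igfbp6 and Ang passed in 1 of 16 settings each, and their adjusted p reached 0.971 in another.

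**Figure D3:**
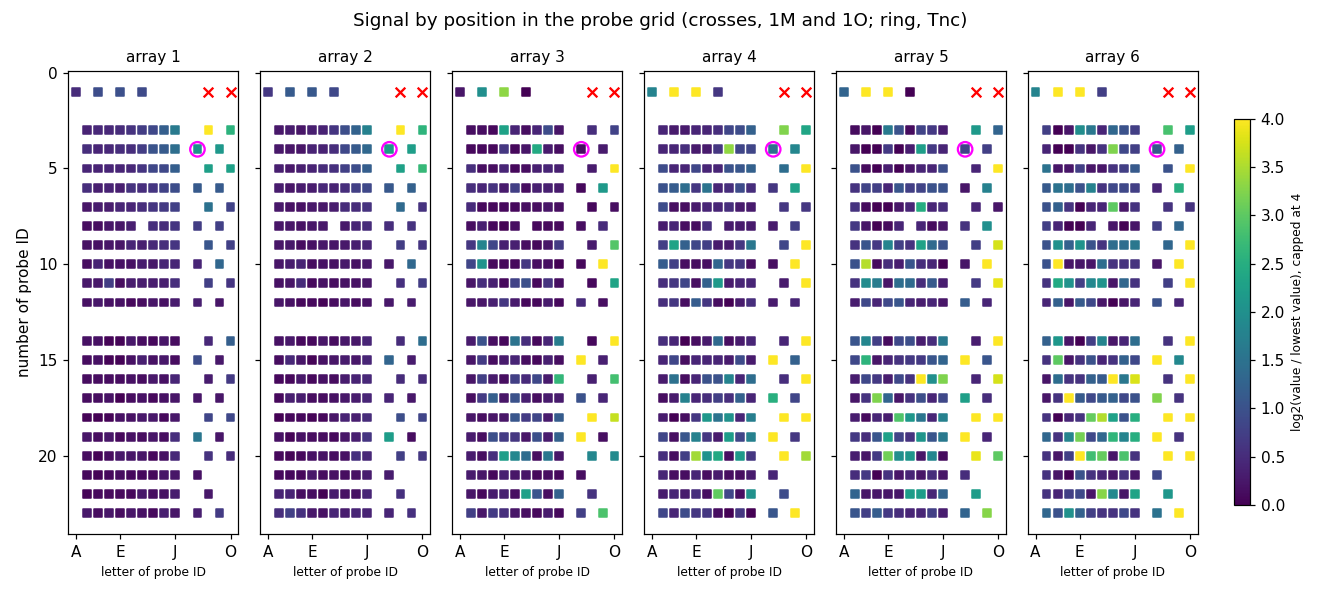
Log2 of the intensity over the array's lowest intensity, capped at 4, at each probe's place in the grid read from its identifier (number as row, letter as column), for the 6 arrays; crosses mark 1M and 1O, and the ring marks Tnc. On arrays 1 and 2 the signal of many probes falls with distance from 1M. In the 151 probes near the lowest intensity on array 3, the correlation across probes of log2 excess with log2 distance was −0.859 and −0.706 there. It was −0.387 on array 4, and 0.076, −0.005 and −0.082 on arrays 3, 5 and 6.

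Members of 6 of 15 gene lists moved together from array to array more than in independent shuffles (permutation tests, 15 lists tested). The shuffles ignore movement shared by genes of like signal, so passing does not by itself set a list apart from such genes. For fast contractile the score variance was 0.98, against medians of 0.31 for shuffles and 0.86 for random lists of like signal. For matrix proteolysis it was 0.32, against 0.06 and 0.41. Percentiles for all 6 lists are given under Other observations. The fast contractile list, 3 myosin heavy chains, had scores of −1.16 and −1.19 on arrays 1 and 2 and of 0.03, 0.903, 0.327 and 1.10 on arrays 3 to 6 (adjusted permutation p = 0.0002, n = 6). Glycolysis and glycogen, 11 genes led by Aldoa, Pgk1 and Ldhb, had −0.774 and −0.875 against 0.475, 0.501, 0.086 and 0.587 (adjusted permutation p = 0.0002, n = 6). The 5 reference genes, led by Rps29, Gapdh and Ywhaz, had −0.893 and −0.691 against −0.102, 1.30, 0.058 and 0.326 (adjusted permutation p = 0.00561, n = 6), but without array 4 they did not pass (ratio of score variance to the median of shuffled values 1.40 against 3.41; adjusted permutation p = 0.543, n = 5). Angiogenesis and endothelium, 19 genes led by Tek (the angiopoietin receptor), Angpt1 and Pdgfa, ran the other way, with 0.773 and 0.421 against −0.256, −0.129, −0.274 and −0.535 (adjusted permutation p = 0.00052, n = 6). With unstandardized scores the ratio fell from 5.28 to 1.65 (adjusted permutation p = 0.289, n = 6). Tek, Angpt1 and Pdgfa reached at most 1.43, 1.33 and 1.53 times the lowest intensity on any array. The list's score variance lay at percentile 78.94 of lists drawn from neighbouring spots, so place on the membrane could account for it. Protein breakdown also stood higher on arrays 1 and 2, with 0.799 and 0.878 against −0.09, 0.419, −0.651 and −1.36 (adjusted permutation p = 0.0261, n = 6). It did not pass without array 1 or 6 (ratios of 2.41 and 1.96 against 2.48, adjusted permutation p = 0.0863 and 0.227, n = 5). Matrix proteolysis, 15 genes led by Plg, Adam8 and Mmp11, had 0.462, 0.563 and 0.421 on arrays 1 to 3 and −0.118, −0.615 and −0.712 on arrays 4 to 6 (adjusted permutation p = 0.0002, n = 6). The 3 leading genes of that list reached at most 1.3 times the lowest intensity on any array, and the ratio fell from 5.45 to 1.41 after subtraction of the lowest intensity and to 1.33 after quantile normalization (adjusted permutation p = 0.393 and 0.45, n = 6). On arrays 3 to 6 alone matrix proteolysis passed (adjusted permutation p = 0.0263, n = 4; 0.0002 to 0.45 over 15 settings) and the other 5 did not. The ratio was close to that with all arrays for fast contractile (3.15 with 6 arrays, 3.20 with 4), matrix proteolysis (5.45, 5.84), reference genes (3.41, 3.08) and protein breakdown (2.48, 2.41), and lower for angiogenesis (5.28, 2.76) and glycolysis (5.47, 1.80). With net values 0 of 6 lists that could be tested passed, fast contractile and glycolysis among them, 1 with an unadjusted permutation p under 0.05. After cyclic loess angiogenesis, matrix proteolysis and the cell cycle list passed, and the scores of reference genes, protein breakdown and matrix proteolysis no longer parted the arrays in this way.

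The 9 lists that did not pass were respiratory chain (adjusted p = 0.898), lipid metabolism (0.19), sarcomere scaffold (0.459), extracellular matrix (0.326), myogenic regulation (0.459), stress (0.918), leukocyte (0.815), immediate early (0.815) and cell cycle (0.815), each by permutation. In list spread, angiogenesis and endothelium was the 1 list outside the limits, with a median SD of 0.94 at percentile 99.97 of matched random lists, whose median was 0.73. The other 14 lists lay between percentiles 3.68 and 86.47. The angiogenesis list lay inside the limits at 97.09 after median-centring, at 93.63 after quantile normalization, at 88.62 after subtraction on all arrays and at 86.06 on arrays 3 to 6, and outside them at 99.11 after cyclic loess. The leukocyte list, at 86.47 here, lay outside them at 98.73 after median-centring, 99.30 after quantile normalization, 99.49 after cyclic loess, 98.15 after subtraction and 99.36 on arrays 3 to 6. Of its measured genes, Il6, Il1b and Il6ra stayed under 2 times the lowest intensity on arrays 3 to 6, and only Il6st passed. The name of this list, here and below, thus does not stand for a signal of leukocytes.

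Relations between list scores across the 6 animals were planned for 8 pairs and could be run for 6, since slow contractile had 1 gene. None passed after adjustment, and 3 had an unadjusted exact permutation p under 0.05. All 3 use the respiratory chain score, whose list did not pass above. Its variance was 0.0626, or 0.488 times the median of shuffled values (2.20 times on arrays 3 to 6, 2.58 unstandardized). With all 6 arrays and standardized scores each r thus rests on a small residue of 7 genes that did not co-vary. Among them Cyct, a testis gene, reached at most 1.67 times the lowest intensity. Ucp3, 2.83 grid steps from 1M, gave 5.93 and 6.07 times on arrays 1 and 2 and 1.72 to 5.11 on the others. Respiratory chain and lipid metabolism gave r = 0.972 (exact permutation p = 0.00833, adjusted 0.05) and rho = 0.943 (exact p = 0.0167, adjusted 0.1), with r = 0.997 without the 2 animals farthest from the median. After cyclic loess the same pair gave r = 0.064. Respiratory chain and glycolysis gave r = 0.817 (exact permutation p = 0.0472, adjusted 0.0944) and rho = 0.886 (exact p = 0.0333, adjusted 0.1), with r = 0.689 without those 2 and −0.171 after cyclic loess. Leukocyte genes and respiratory chain gave r = −0.943 (exact permutation p = 0.0236, adjusted 0.0708) and rho = −0.771 (exact p = 0.103, adjusted 0.206), with r = −0.886 without the 2 farthest. The sign of that pair turned in 3 of 14 settings, with r = 0.066 after quantile normalization, 0.218 after cyclic loess and 0.396 with unstandardized scores. The 3 pairs with extracellular matrix gave r = 0.34 with matrix proteolysis, −0.27 with myogenic regulation and 0.046 with leukocyte genes (rho = 0.371, −0.6 and −0.257; exact permutation p for r = 0.488, 0.622 and 0.883, adjusted 0.731, 0.747 and 0.883; for rho 0.497, 0.242 and 0.658). Their signs turned in 2, 2 and 9 of 14 settings. Without the dimmest quartile of probes the pair with matrix proteolysis gave r = 0.832 (adjusted exact permutation p = 0.1, n = 6) and rho = 0.943 (adjusted exact permutation p = 0.0333, n = 6). On arrays 3 to 6 alone respiratory chain gave r = 0.972 with lipid metabolism, 0.515 with glycolysis and −0.900 with leukocyte genes (exact permutation p = 0.0417, 0.542 and 0.0833, adjusted 0.25, 1.0 and 0.25, n = 4). The matrix pairs gave 0.176, 0.385 and −0.021 there, each with an adjusted exact permutation p of 1.0 (n = 4). With net values respiratory chain gave r = −0.068 with lipid metabolism and 0.111 with glycolysis over the genes left (adjusted exact permutation p = 0.917 for both, n = 4). With 4 arrays an exact permutation p for r cannot fall below 0.0417. A lone relation could thus not pass after adjustment there, and these p-values do not show that a relation is absent.

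Agreement between arrays followed the same split. Across the 197 probes, which are not independent replicates, the median correlation of the 15 pairs was 0.516, with a range of 0.295 to 0.970. Arrays 1 and 2 correlated at 0.957 with each other and held equal intensities at 22 of 221 probes. The pairs within arrays 3 to 6 lay between 0.872 and 0.970, and the highest, arrays 5 and 6, gave 0.981 with net values.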

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

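The test of spreading from bright spots was chosen after the result was seen. Probes 1M and 1O take no part in the comparisons above, and each gave an intensity far above the other probes, whose highest intensity on any array was 0.143: 36.6 for 1M and 4.84 for 1O, the ribosomal RNA probe, both as the highest of 6 arrays. Of 62 values tested for a lone animal far from the others, 0 passed, where chance gives about 5%. Arrays 1 and 2 correlated at 0.957 with each other across probes. Where they stood apart together, each hid the other from this test. The count of 0 thus does not show that no animal stood apart.

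In uncentred values Top1, Tnc, Dgat1 and Fgfr3 varied more than probes of like signal, with their high values on arrays 1 and 2, the arrays on which 1M gave 36.6 and 35.7. A candidate explanation is label or light from 1M and 1O reaching spots close to them. Against a trend of signal with grid distance, fitted on 151 other probes, Top1 lay 0.89 and 1.28 residual SDs above on arrays 1 and 2. Tnc, Dgat1 and Fgfr3 lay between 0.28 and 0.96 below, all within 2 residual SDs. Among tested probes within 4.0 grid steps of 1M, the fit used only Pole2, so it leaned on probes farther out. The residual SDs were 0.674 and 0.775 log2, a wide window, so the fit leaves spreading open without establishing it. No biological explanation was tested for the 4 genes, since the design gives 1 group, and transcript from the Tnc locus in some animals stays open.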

How the results depend on the processing

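The settings with arrays 3 to 6 alone, with the lowest intensity subtracted, and with 1M and 1O kept were chosen after the data were seen. A floor 2 times as high left 5 probes measured on all 6 arrays, and 30 on arrays 3 to 6. The mean log2 intensity of Tnc was 0.75 after median-centring and 1.46 after subtraction and centring, by construction of those scales. The median SD was 0.29 after median-centring, 0.28 after quantile normalization, 0.20 after cyclic loess, 0.52 on arrays 3 to 6 and 0.47 with net values. The median correlation between arrays was 0.895 on arrays 3 to 6, 0.862 with net values and 0.806 after cyclic loess, and 0.392 to 0.874 with 1 array left out. Hypervariable genes, 4 with all arrays, numbered 1 after median-centring, 1 with a prior that is not robust, and 0 with a prior without a trend, with quantile normalization, with cyclic loess, and after subtraction on all arrays or on arrays 3 to 6. They numbered 0 to 6 with 1 array left out (0 without array 1, 2 or 6, and 1 without array 3); unadjusted p-values under 0.05 numbered between 0 and 15 in limma's test over all settings. Co-varying gene lists, 6 with all arrays, numbered 7 after subtraction on all arrays (less matrix proteolysis and protein breakdown, plus lipid metabolism, extracellular matrix and cell cycle), 7 with unstandardized scores (less angiogenesis, plus respiratory chain and sarcomere scaffold), 4 with quantile normalization (less matrix proteolysis, protein breakdown and reference genes, plus extracellular matrix), 4 with a pseudocount (less protein breakdown and reference genes), 4 without the dimmest quartile (less matrix proteolysis and reference genes), 5 to 6 with 1 array left out (protein breakdown lost without array 1 or 6, reference genes without array 4), 1 on arrays 3 to 6, 3 after cyclic loess, and 0 with net values, where 2 of the 6 could be tested; on arrays 3 to 6 the score-variance ratio was close to that of all arrays for 4 lists. With 4 arrays 34 of 60 simulated lists with a shared factor were called; reference genes passed in 9 and protein breakdown in 8 of 15 settings, the other 4 in 12 or more. Relations between gene lists, 0 with all arrays, numbered 2 without the dimmest quartile, 2 with unstandardized scores, and 1 each with a pseudocount, with quantile normalization and after subtraction on all arrays; by rho they numbered 3 without the dimmest quartile, extracellular matrix with matrix proteolysis (r = 0.832) among them. Lists outside the limits of spread, 1 with all arrays, numbered 2 after median-centring, 3 after subtraction on all arrays, 4 after cyclic loess, 0 with net values, and 1 to 2 with 1 array left out (2 without array 1, 4 or 6); angiogenesis was not among them after median-centring, quantile normalization or subtraction, and leukocyte genes were. The cause of these differences was not tested beyond the removal of arrays and probes that each setting makes. For single named genes and relations, 486 values stayed within their limits, 167 moved, 7 relations passed only in the alternative, and 18 values of r turned sign, none past the threshold. Extracellular matrix with leukocyte genes, r = 0.046 with all arrays, turned in 9 of 14 settings: −0.021 on arrays 3 to 6, −0.169 with a pseudocount, −0.025, −0.024 and −0.283 without array 1, 5 or 6 (up to 0.299 without array 3), −0.23 after subtraction on all arrays, −0.172 after quantile normalization, −0.756 after cyclic loess and −0.705 with unstandardized scores. Leukocyte genes with respiratory chain turned to 0.066 with quantile normalization, 0.218 after cyclic loess and 0.396 with unstandardized scores. Respiratory chain with glycolysis turned to −0.171 after cyclic loess, with lipid metabolism to −0.068 with net values, extracellular matrix with matrix proteolysis to −0.165 after subtraction and −0.231 with quantile normalization, and with myogenic regulation to 0.266 without array 3 (−0.553 to 0.266 with 1 array left out) and 0.385 on arrays 3 to 6. The cause was not tested. Median-centring cannot move list scores, relations or correlations and normalization cannot move the count of probes measured; with net values 2 of 6 relations could be run. The test against a reference was not run. Signal over background limits arrays 1 and 2 most, where Myh1, Myh2, Myh4, Des and Ttn stayed under 2 times the lowest intensity.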

Other observations

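The tests of signal level and of arrays 1 and 2 were chosen after the results were seen, while those of position for the gene lists and of neighbouring spots were not. The genes named for single arrays were also chosen after their values were seen.

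Cdh5, Pecam1, Igf1, Igfbp6, Il6st and Ccna1 stood further above the lowest intensity on arrays 5 and 6 than on arrays 3 and 4. Folds depend on each array's lowest intensity, and the probes at 2 times it numbered 37 and 64 on arrays 3 and 4 and 77 and 104 on arrays 5 and 6. Cdh5 and Pecam1, junction proteins of endothelial cells, lay at 1.44 and 1.5 times on array 3, 1.56 and 1.89 on array 4, 3.75 and 4.58 on array 5, and 5.33 and 4.33 on array 6. Igf1 gave 1.22, 1.33, 3.92 and 3.0 times at probe 16I and 2.06, 1.78, 4.58 and 3.67 at probe 22H. Igfbp6 gave 1.83, 3.44, 15.8 and 20.5 times, Il6st 2.28, 3.33, 9.33 and 18.7, and the cyclin Ccna1 1.61, 1.78, 6.0 and 8.0. Ldhc, known mainly from testis, gave 1.39, 1.67, 3.92 and 2.5, and Slc2a2, known from liver and pancreas, 1.22, 1.78, 2.08 and 3.5, while Tek gave 1.11, 1.33, 1.33 and 1.33. The titles of arrays 5 and 6 carry the numbers 198 and 199, and those of arrays 1 to 4 the numbers 179 to 182; whether these mark batches is not given in the sources used here. With 2 arrays against 2 no test was run.

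Array 4 stood below the other 3 for another set of genes. Igf2 gave 2.67 times the lowest intensity on array 4 and 6.28, 9.33 and 13.7 on arrays 3, 5 and 6. Ang gave 1.33 against 4.94, 3.08 and 3.83, and Cdk4, a kinase of the cell cycle, 1.33 against 3.17, 3.08 and 2.67. On the same array Myh7 and Myh2 gave 77.0 and 32.9 times, the highest of the 4 arrays for each gene.

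Of 9 probes for genes known mainly from testis, placenta, intestine, liver or pancreas, 0 reached 2 times the lowest intensity on each of arrays 3 to 6. Ldhc, a lactate dehydrogenase, and Slc2a2, a glucose transporter, did so on arrays 5 and 6, with the values given above. The other 7, among them Plg, Gip and Pdha2, stayed under 2 times on all of arrays 3 to 6. These values give the size of signal seen on single arrays for genes not known from muscle.

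The 6 co-varying lists were set against random lists of like signal, because a floor that differs between arrays could move dim and bright genes apart; a biological difference was not tested, since there is 1 group. For angiogenesis a differing floor is argued against only weakly as the whole cause. The list lay at percentile 99.95 of the score variance, with a ratio to shuffled values of 5.28. The ratio was 5.99 after cyclic loess and 6.91 after subtraction of the lowest intensity. With unstandardized scores it was 1.65 and the list did not pass. The leading genes Tek, Angpt1 and Pdgfa reached at most 1.43, 1.33 and 1.53 times the lowest intensity, so the standardized scores rest on small differences near the floor. A differing floor stays open for the other 5, at percentiles 91.79 (fast contractile), 99.8 (glycolysis), 89.61 (reference genes), 95.45 (protein breakdown) and 21.9 (matrix proteolysis). The first 3, with ratios of 3.15, 5.47 and 3.41, did not pass after cyclic loess (1.34, 1.20 and 2.41) but did after subtraction (3.17, 7.91 and 2.88). Protein breakdown (2.48) passed after neither (1.17 and 1.56). Matrix proteolysis (5.45) passed after cyclic loess (4.60) but not after subtraction (1.41) or quantile normalization (1.33). Its score variance of 0.32 was below the 0.41 median of lists of like signal (0.06 for shuffled values), so it co-varied no more than other genes of like signal. The angiogenesis list lay at percentile 78.94 of lists of grid neighbours (score variance 0.24, their median 0.15), under the limit of 90. Place on the membrane could thus account for its co-variation. The glycolysis list lay at 99.6. Arrays 1 and 2 as the cause stay open for all 6 lists, with ratios on arrays 3 to 6 of 3.20 (fast contractile), 3.08 (reference genes), 2.41 (protein breakdown), 2.76 (angiogenesis), 1.80 (glycolysis) and 5.84 (matrix proteolysis, the 1 list to pass there, with 13 of 17 probes under 2 times the lowest intensity on all 4 arrays).

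Igfbp6, Ang and the unnamed 10C and 1C were the hypervariable probes of arrays 3 to 6, with SDs of 1.33, 1.22, 1.43 and 1.23. A flaw in 1 region of the membrane was argued against for Igfbp6 and 10C, with 8 neighbouring spots each, and only weakly for Ang, with 2. Of these 3 probes, 0 had neighbours of unusual spread (median SDs of 0.61 for Ang, 0.43 for Igfbp6 and 0.57 for 10C, against a limit of 0.68). Probe 1C has no neighbours. A flaw of a single spot would not show in a median over its neighbours. Differences between animals in Igfbp6 and Ang are a hypothesis that may be followed up, and other causes stay open, among them batches behind the title numbers for Igfbp6; Ang was low on array 4 alone.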
